A study of Homo sapiens with 22 samples.

How the data were processed

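The series holds 22 RNA sequencing libraries of human multiple myeloma cells treated for 24 h with APY0201, an inhibitor of the lipid kinase PIKfyve, or with the vehicle DMSO. There are 5 established myeloma lines (KMS26, L363, EJM, JJN3 and RPMI-8226) with vehicle and 100 nM, which gives 10 libraries, and cells of 4 donors with vehicle, 50 nM and 500 nM, which gives 12 libraries. In the lines, replicate 1 is KMS26, replicate 2 JJN3, replicate 3 L363, replicate 4 EJM and replicate 5 RPMI-8226. Per the labels, RNA of the lines was prepared with an RNeasy Plus kit and RNA of the patient samples with an AllPrep kit. Each line or donor was treated with every dose of its set, so each is its own control.

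The 1 processed table of the series was used, with 64253 entries on the hg38 build, each with an Ensembl identifier that the table itself pairs with a symbol. The labels do not state the unit, which was read from the values. The 10 line columns hold TPM computed by the authors: each column sums to 1000000. The 12 patient columns hold RPKM computed by the authors: each value times the gene length plus 1 base is a whole multiple of a step that is fixed for each library. Per the submitters' processing notes, STAR 2.5.2b, featureCounts and Subread were used with hg38; their roles and the normalization step are not given in the sources used here. The strandedness of the libraries is not stated, so entries that overlap another gene, such as small RNA genes and antisense transcripts inside longer genes, may carry reads of that gene.

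The steps of the RPKM columns gave back the reads assigned per patient library, between 36.9 and 57.2 M reads. TPM keeps no such step, so the depth of the line libraries is unknown. The analysis planned before the data were examined expected read counts, with a moderated linear model on log2 values as the fallback; the fallback was used. The plan named a scaling factor of the TMM kind as the main choice for counts, and the fallback named no scaling. TMM was kept, and the number of changed genes in the lines with values as deposited had been seen when this was settled, so that number stands beside the line result.

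Entries were left out if they can differ by person (1491 entries: chromosome Y, HLA genes, variable segments of immunoglobulins and T cell receptors, and similar). A further 4146 entries lie on alternate or unplaced contigs; for genes that also have such entries the report gives their number. No 2 columns of the table were identical. Genes were tested with a value of at least 0.5 in at least 5 of the line libraries (16388 genes) or at least 4 of the patient libraries (17913 genes). TMM factors were computed separately for lines and patient samples, without precision weights. They trimmed 30 percent of the log ratios and 5 percent of the levels from each end. A pseudocount of 0.5 was added before log2.

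Tests used limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along a trend in mean level and with the line or donor as a block. They were two-sided, apart from the overlap test below. Lines were fitted alone, and the 12 patient libraries together. Adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The differences of the line response from the patient responses came from a fit of all 22 libraries with 9 blocks, over the 14030 genes tested in lines and in patient samples. These compare changes alone, since TPM and RPKM levels were never set side by side. The joint fit gives each gene a shared residual variance and so assumes equal spread in lines and donors. The plan kept the other fits apart because that spread was taken to differ, so p values of the differences depend on this assumption. The 50 nM and 500 nM comparisons share their vehicle libraries, so no overlap between them is given. The overlap of line and patient genes used Fisher's exact test, for an excess of shared genes alone, across genes, which are not independent of each other. Standard errors are moderated errors of the log2 change.

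The 38 gene lists were written before the data were examined. They cover phosphoinositide enzymes, the lysosome, autophagy, sterol and fatty acid metabolism, protein folding and other stress, growth, mitochondria, plasma cell identity and markers of 8 other cell types. A list was tested with camera at a preset correlation of 0.01 where at least 5 members were tested: 30 lists in lines and 35 in each patient comparison. The adjusted p over lists was then recomputed with an estimated correlation, and with fry. Camera with an estimated correlation rests on the residual degrees of freedom, 4 in the line fit and 6 in the patient fit. A miss there thus does not show that a list is unchanged. Counts of list members are given over all genes, and adjusted over the list alone. A symbol with 2 tested entries counts as 2 members, as for IDS among hydrolases, CLN3 among lysosomal membrane proteins, IRF9 among interferon genes and, in patient samples, ITGB3 among megakaryocyte markers. Shares of a library in groups of genes were compared by exact sign-flip permutation over pairs, whose smallest p is 0.0625 with 5 pairs and 0.125 with 4 pairs.

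Genes named in the text follow a rule fixed before the data were examined. They are 6 control genes (PIKFYVE, FIG4, VAC14, TFEB, TFE3 and MITF); the 6 largest rises and 6 largest falls past the threshold with a mean log2 level of at least 1 and the same direction in every line or donor; and up to 4 members with the smallest p of each list described. For tests of a difference the rule takes the 4 largest in each direction. Genes named outside the rule are said to be, and 3 genes that the rule takes are not reported here. Means of levels are means of the deposited values.

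The pairing of libraries was checked by correlating log2 levels after removing each gene's mean within each treatment group. That step in itself lowers correlations between different lines or donors. Libraries of 1 line correlated at 0.850 to 0.909 and libraries of different lines at 0.138 at most. For donors these were 0.819 to 0.958 and 0.0265. The fit was tested on simulated data with 200 changed genes per comparison. Each gene had independent normal noise of its own fitted spread around the line or donor means, and the other genes had no change. Real genes vary together, so the shares and false calls below hold for that setting alone. It called 51.5% of genes with a log2 change of 0.5, 69.7% at 1 and 89.4% at 2 in the lines, 50.0%, 83.3% and 97.0% at 50 nM, and 52.9%, 84.8% and 93.9% at 500 nM. False calls numbered 7, 7 and 9.

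The alternatives tried were median-of-ratios scaling, no filter on low values, immunoglobulin genes left out before scaling, no replicate block, each line or donor left out in turn, limma-voom on the recovered reads of the patient samples, and only the 8 libraries compared. Other alternatives were added after the data were seen: no scaling at all, pseudocounts of 0.1 and 1, protein-coding genes alone, and the lines in 2 sets by their content of a ribosomal RNA repeat entry. Counts were also set beside those of up to 100 other splits of the same libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.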

Results

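The data are gene expression levels of human multiple myeloma cells 24 h after treatment with APY0201, which inhibits PIKfyve, the kinase that makes the phosphoinositide PI(3,5)P2 on endosomes and lysosomes. There are 5 established myeloma lines, cells kept growing in culture, with 1 vehicle and 1 treated library each at 100 nM. There are also primary samples of 4 patients, called donors here, with no cell sort given in the labels, each with vehicle, 50 nM and 500 nM. The patient libraries hold 36.9 to 57.2 M assigned reads, and the depth of the line libraries is unknown. Levels are deposited TPM in lines and deposited RPKM in patient samples, and changes are log2 changes with 1 standard error, paired within line or donor.

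In the 5 lines at 100 nM, the genes that rose include RRAGC and FLCN, of the nutrient-sensing machinery of the lysosome, NEU1, of its hydrolases, and MVD, the only 1 of 24 sterol genes past the threshold over all genes. RRAGC, a Rag GTPase that recruits mTORC1 and TFEB to the lysosome (chromosome 1, 38838198 to 38859823), rose by 1.53 ± 0.16 (mean 6.61 to 18.8 TPM, 5 of 5 lines, adjusted p = 0.0472). FLCN, the folliculin subunit that acts on Rag GTPases (chromosome 17, 17212212 to 17237188), rose by 1.35 ± 0.15 (10.4 to 28.7 TPM, 5 of 5, adjusted p = 0.0472). NEU1, a lysosomal sialidase (chromosome 6, 31857659 to 31862906, with 7 more entries on other contigs), rose by 1.47 ± 0.08 (108 to 304 TPM, 5 of 5, adjusted p = 0.020). MVD, an enzyme of the mevalonate pathway (chromosome 16, 88651935 to 88663161), rose by 1.26 ± 0.12 (11.7 to 26.8 TPM, 5 of 5, adjusted p = 0.0472).

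Other large rises in the lines, each in 5 of 5, were partly in short or non-coding entries. The entry mascRNA-menRNA, which lies inside MALAT1, rose by 2.005 ± 0.21. LINC01480 rose by 1.68 ± 0.19, LGMNP1, a pseudogene of legumain, by 1.67 ± 0.17, and LRRC14B by 1.56 ± 0.15 (adjusted p = 0.0472 for these 4). MIR616, which lies inside the stress gene DDIT3, rose by 1.56 ± 0.18 (adjusted p = 0.0489), and DDIT3 itself was at 1.07 ± 0.13 (adjusted p = 0.0502). Among 5 falls were NCAPD2, a condensin subunit, at −0.43 ± 0.05 (adjusted p = 0.0472), and LMNB1, a lamin of the nuclear envelope, at −0.37 ± 0.04 (adjusted p = 0.0489). The other 3 falls, named after their values were seen, were the clone-named entries AL365502.1 (−1.61), RP1-152L7.5 (−0.55) and RP5-1160K1.6 (−0.45).

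The genes of the PIKfyve complex itself did not pass the test in the lines. PIKFYVE was at 0.07 ± 0.08 (adjusted p = 0.620), its scaffold VAC14 at 0.38 ± 0.06 (adjusted p = 0.0683), and the lysosomal transcription factors TFEB and TFE3 at 0.15 ± 0.12 and 0.08 ± 0.08 (adjusted p = 0.485 and 0.569). FIG4 and MITF were too low to test. Of 11 tested phosphoinositide enzymes, 1 rose over all genes, PIP4K2C, a PI5P 4-kinase (0.54 ± 0.06, adjusted p = 0.0472), and 2 rose adjusted over the list alone (camera adjusted p = 0.151).

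Lysosomal lists had medians above 0 in the lines. Of 26 entries for lysosomal membrane proteins, of which CLN3 has 2, 5 rose over all genes, and 19 rose and 1 fell adjusted over the list alone (median 0.46, camera adjusted p = 1.02e-11). The same list had adjusted p = 0.412 with an estimated correlation. The list also holds NPC2, a soluble protein that carries cholesterol inside the lysosome, which rose by 1.42 ± 0.16. The chloride exchanger CLCN7 rose by 0.89 ± 0.09, the sialic acid carrier SLC17A5 by 0.80 ± 0.06 and the phosphoinositide phosphatase TMEM55B by 0.62 ± 0.06 (adjusted p = 0.0472 for each). Of 38 entries for lysosomal hydrolases and their activators, of which IDS has 2, 3 rose over all genes and 24 adjusted over the list alone (median 0.30, camera adjusted p = 2.46e-12, adjusted p = 0.412 with an estimated correlation). They include NEU1 and the saposin precursor PSAP, at 0.69 ± 0.07. The cysteine protease LGMN had a larger value that missed the threshold, 2.38 ± 0.31 (adjusted p = 0.0569). Of 18 subunits of the vacuolar ATPase, the proton pump, 0 rose over all genes in limma and 14 adjusted over the list alone (median 0.39, camera adjusted p = 3.13e-10, adjusted p = 0.412 with an estimated correlation). ATP6V0A1 was at 0.56 and ATP6V0D1 at 0.51.

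Regulators of TFEB and autophagy genes were part of the same picture in the lines. Of 13 members of the TFEB family and its direct regulators, 2 rose over all genes, RRAGC and FLCN, and 6 adjusted over the list alone (median 0.20, camera adjusted p = 3.31e-05, adjusted p = 0.412 with an estimated correlation). The folliculin partner FNIP1 was at 0.65 (adjusted p = 0.0569). Of 35 autophagy genes, 1 rose over all genes, VPS18, a subunit of lysosomal tethering complexes (0.64 ± 0.07, adjusted p = 0.0472), and 12 adjusted over the list alone (median 0.13, camera adjusted p = 1.13e-07, adjusted p = 0.412 with an estimated correlation). The autophagosome protein MAP1LC3B was at 0.57 (adjusted p = 0.0711) and the receptor OPTN at 1.04 (adjusted p = 0.0719). Of 32 endosomal genes, 1 rose over all genes, M6PR, a receptor that sorts hydrolases to the lysosome (0.58 ± 0.06, adjusted p = 0.0472), and 6 adjusted over the list alone (median 0.07, camera adjusted p = 0.000651, adjusted p = 0.412 with an estimated correlation).

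Sterol genes had the highest median of the lists tested in the lines. Of 24 genes of cholesterol synthesis and uptake, 1 rose over all genes, MVD, and 22 rose and 1 fell adjusted over the list alone (median 0.89, camera adjusted p = 3.34e-14, adjusted p = 0.412 with an estimated correlation). INSIG1, a sterol sensor of the endoplasmic reticulum, was at 1.995 ± 0.26 (adjusted p = 0.0569) and HMGCS1, the synthase that makes HMG-CoA, at 1.80 ± 0.27 (adjusted p = 0.0638). Of 15 genes of fatty acid synthesis, 1 rose over all genes, ACSS2, which makes acetyl-CoA from acetate (0.71 ± 0.06, adjusted p = 0.0472), and 3 adjusted over the list alone (median 0.12, camera adjusted p = 0.000229, adjusted p = 0.412 with an estimated correlation).

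Growth lists had medians below 0 in the lines, with 0 members past limma's threshold over all genes. Adjusted over the list alone, 25 of 32 genes of MYC and ribosome biogenesis fell (median −0.31, camera adjusted p = 1.08e-12), 20 of 33 genes of G2 and M phase (median −0.23, camera adjusted p = 4.75e-10) and 9 of 38 genes of DNA replication (median −0.19, camera adjusted p = 3.57e-10). For these 3 lists adjusted p = 0.412 with an estimated correlation. Examples are BOP1, a ribosome assembly factor, at −0.42 (adjusted p = 0.0997), KIF20A, a mitotic kinesin, at −0.45 (adjusted p = 0.0711), and MCM3, a subunit of the replicative helicase, at −0.41 (adjusted p = 0.0677). Heat shock genes were at a median of −0.24, with 0 of 13 past the threshold over all genes in limma and 5 lower adjusted over the list alone (camera adjusted p = 0.000229, adjusted p = 0.412 with an estimated correlation). The chaperone HSP90AA1 was at −0.24 (adjusted p = 0.0944).

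Over all genes in the lines, limma called 54 of 16388, 49 higher and 5 lower, 37 of them protein-coding and 16 at least 2-fold higher. At an unadjusted p under 0.05 there were 3688, and 19 of 30 lists passed with the preset correlation against 0 with an estimated correlation. The call of 54 rests on the settings. It was 0 with values as deposited (smallest adjusted p = 0.0663), 0 without the block on line, 0 with no filter on low values, 0 without any 1 of KMS26, L363, EJM, JJN3 or RPMI-8226, 2 with a pseudocount of 0.1, and 816, 528 higher and 288 lower, when protein-coding genes alone were fitted. Without genes shorter than 300 bases 231 protein-coding genes passed, 176 of them higher, against 35 of 37 in the full fit, so the share that rose also rests on the settings. The call of every line gene named here was lost in the settings that gave 0.

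In patient samples at 500 nM, 22 of 24 sterol genes, 15 of 19 oxidative stress genes and 6 of 13 heat shock genes rose over all genes, and 10 of 23 plasma cell genes and 32 of 48 ribosomal protein genes fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.119 to 0.387). INSIG1 (chromosome 7, 155297776 to 155310235) rose by 2.18 ± 0.26 (44.7 to 200 RPKM, 4 of 4 donors, adjusted p = 0.00343). SQSTM1, the autophagy receptor p62 (chromosome 5, 179806398 to 179838078), rose by 1.35 ± 0.13 (143 to 380 RPKM, 4 of 4, adjusted p = 0.00256). FCRL5, a surface receptor of plasma cells (chromosome 1, 157513377 to 157552520), fell by 1.20 ± 0.14 (4 of 4, adjusted p = 0.00343).

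Other large rises at 500 nM, each in 4 of 4 donors, were a chemokine and chaperones. CCL3, an inflammatory chemokine (chromosome 17, 36088256 to 36090169, with 2 more entries on other contigs), rose by 3.06 ± 0.48 (5.995 to 43.9 RPKM, adjusted p = 0.00745; without replicate 1 adjusted p = 0.0539). HSPA6 rose by 2.38 ± 0.46 (4.43 to 50.5 RPKM, adjusted p = 0.0132). HSPA1B rose by 1.95 ± 0.35 (adjusted p = 0.0107) and HSPA1A by 1.93 ± 0.39 (chromosome 6, 31815464 to 31817946, adjusted p = 0.0150). These 3 encode inducible HSP70 chaperones, and HSPA1A and HSPA1B are near-identical copies whose reads cannot be assigned cleanly. Without replicate 1, 2 or 3 they missed the threshold: HSPA6 at adjusted p = 0.0805, 0.0896 and 0.0770, HSPA1B at 0.0741, 0.0825 and 0.0668, and HSPA1A at 0.0957, 0.101 and 0.0803.

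The large falls at 500 nM, each in 4 of 4 donors, include genes of cell types other than plasma cells. PRG3 and PRG2, granule proteins of eosinophils, fell by 2.32 ± 0.56 and 1.77 ± 0.48 (adjusted p = 0.0280 and 0.0402). The chemokine receptor CCR2 fell by 2.06 ± 0.27 (adjusted p = 0.00500), and the integrin ITGA8 by 1.64 ± 0.38 (adjusted p = 0.0246). SPP1, which encodes osteopontin, fell by 1.39 ± 0.17 (adjusted p = 0.00387), and SNORD50B, inside its host SNHG5, by 1.44 ± 0.39 (adjusted p = 0.0394). Without replicate 1, 2 or 3, adjusted p was 0.142, 0.105 and 0.123 for PRG3 and 0.181, 0.114 and 0.159 for PRG2. ITGA8 missed the threshold without replicate 2 or 3 (0.0970 and 0.0860), and SNORD50B without any 1 of replicates 1 to 4 (0.0858, 0.108, 0.0619 and 0.0905). Without replicate 3 the change of SNORD50B was −0.84, and without replicate 1 that of ITGA8 was −1.01.

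Of the control genes at 500 nM, VAC14 rose by 0.51 ± 0.12 (adjusted p = 0.0228) and TFE3 by 0.31 ± 0.08 (adjusted p = 0.0321), each in 4 of 4 donors. PIKFYVE was at 0.15 ± 0.09 (adjusted p = 0.288), FIG4, the phosphatase of the complex, at 0.06 ± 0.10 (adjusted p = 0.705) and TFEB at 0.03 ± 0.10 (adjusted p = 0.862), and MITF was too low to test. VAC14 missed the threshold without any 1 of replicates 1 to 4 (adjusted p = 0.117, 0.0510, 0.0675 and 0.0904), and TFE3 without replicate 1, 2 or 3 (0.0939, 0.146 and 0.119). TFEB was at −0.087 without replicate 3, and FIG4 at −0.043 without replicate 4. Of 12 phosphoinositide enzymes, 3 rose and 1 fell over all genes, and 6 rose and 1 fell adjusted over the list alone (median 0.19, camera adjusted p = 0.00943, adjusted p = 0.329 with an estimated correlation).

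Lysosomal and autophagy genes at 500 nM moved in more than 1 direction. Of 43 entries for the 42 lysosomal hydrolases on the list, of which IDS has 2, 3 rose and 5 fell, over all genes and adjusted over the list alone (median 0.08, camera adjusted p = 0.287). GLA, the alpha-galactosidase, rose by 0.998 ± 0.09 (adjusted p = 0.00250) and NEU1 by 0.94 ± 0.15 (adjusted p = 0.00805), while the mannosidase MAN2B1 fell by 0.44 ± 0.08 (adjusted p = 0.0116). Of 28 entries for membrane proteins, 5 rose and 2 fell over all genes, and 10 rose and 2 fell adjusted over the list alone (median 0.26, camera adjusted p = 0.00138, adjusted p = 0.388 with an estimated correlation). Their median was 0.12 without replicate 4. NPC1, the cholesterol exporter, rose by 0.92 ± 0.15 (adjusted p = 0.00745), and TPCN1, an ion channel gated by PI(3,5)P2, fell by 0.61 ± 0.07 (adjusted p = 0.00343). Of 18 vacuolar ATPase subunits, 10 rose over all genes and 11 adjusted over the list alone (median 0.36, camera adjusted p = 4.50e-05, adjusted p = 0.329 with an estimated correlation). ATP6V1D rose by 0.60 ± 0.08 (adjusted p = 0.00528). NEU1 missed the threshold without replicate 1 or 3 (adjusted p = 0.0555 and 0.0589), and MAN2B1 without replicate 1, 2 or 3 (0.0564, 0.0901 and 0.0556).

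Among the TFEB family and its regulators at 500 nM, 5 of 14 rose, over all genes and adjusted over the list alone (median 0.24, camera adjusted p = 0.000697, adjusted p = 0.190 with an estimated correlation). FLCN rose by 1.002 ± 0.12 (adjusted p = 0.00343), FNIP1 by 0.80 ± 0.12 (adjusted p = 0.00704) and RRAGC by 0.94 ± 0.16 (adjusted p = 0.00861; without replicate 1 or 3 adjusted p = 0.0534 and 0.0560). Of 37 autophagy genes, 9 rose and 2 fell over all genes, and 11 rose and 2 fell adjusted over the list alone (median 0.13, camera adjusted p = 0.000565, adjusted p = 0.190 with an estimated correlation). MAP1LC3B rose by 0.77 ± 0.12 (adjusted p = 0.00745; without replicate 1 adjusted p = 0.0560). Of 32 endosomal genes, 7 rose and 1 fell over all genes, and 11 rose and 1 fell adjusted over the list alone (median 0.15, camera adjusted p = 6.16e-05, adjusted p = 0.190 with an estimated correlation). The late endosome GTPase RAB7A rose by 0.56 ± 0.07 (adjusted p = 0.00387).

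Lipid synthesis genes rose at 500 nM. Of 24 genes of cholesterol synthesis and uptake, 22 rose, over all genes and adjusted over the list alone (median 1.27, camera adjusted p = 1.82e-17, adjusted p = 0.318 with an estimated correlation). HMGCS1 rose by 1.91 ± 0.21 (adjusted p = 0.00317). Of 15 genes of fatty acid synthesis, 9 rose over all genes and 13 adjusted over the list alone (median 0.41, camera adjusted p = 2.62e-07, adjusted p = 0.262 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose by 1.68 ± 0.24 (adjusted p = 0.00554), FASN, the fatty acid synthase, by 1.16 ± 0.16 (adjusted p = 0.00549) and ACACA, the acetyl-CoA carboxylase, by 0.58 ± 0.07.

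Stress genes at 500 nM rose in several lists. Of 19 NRF2 and oxidative stress genes, 15 rose over all genes and 17 adjusted over the list alone (median 0.65, camera adjusted p = 2.00e-10, adjusted p = 0.190 with an estimated correlation). The sulfiredoxin SRXN1 rose by 0.99 ± 0.10 (adjusted p = 0.00250) and the thioredoxin TXN by 0.76 ± 0.10 (adjusted p = 0.00444). Of 13 heat shock genes, 6 rose over all genes and 10 adjusted over the list alone (median 0.997, camera adjusted p = 4.08e-05, adjusted p = 0.387 with an estimated correlation). Donor medians ran from −0.11 to 2.08, and the list median was 0.64 without replicate 2. Of 32 ATF4 targets, 8 rose over all genes and 11 adjusted over the list alone (median 0.17, camera adjusted p = 0.000472, adjusted p = 0.524 with an estimated correlation). ATF3 rose by 1.51 ± 0.14 (adjusted p = 0.00250), the phosphatase subunit PPP1R15A by 1.12 ± 0.12 and the cytokine GDF15 by 1.31 ± 0.16. The median of the ATF4 list was 0.34 without replicate 1 and 0.059 without replicate 3. Of 30 genes of the unfolded protein response, 10 fell over all genes and 11 adjusted over the list alone (median −0.16, camera adjusted p = 4.08e-05, adjusted p = 0.329 with an estimated correlation). Of these DERL3, a factor of protein degradation from the endoplasmic reticulum, fell by 0.70 ± 0.07 (adjusted p = 0.00287) and the disulfide isomerase PDIA4 by 0.42 ± 0.05 (adjusted p = 0.00400). The median of that list was −0.084 without replicate 1 and −0.25 without replicate 4.

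Plasma cell genes fell at 500 nM beside markers of myeloid cells. Of 23 plasma cell identity genes, 1 rose and 10 fell over all genes, and 1 rose and 15 fell adjusted over the list alone (median −0.46, camera adjusted p = 1.22e-05, adjusted p = 0.119 with an estimated correlation). CD27, a costimulatory receptor, fell by 0.60 ± 0.07 (adjusted p = 0.00373), and MZB1, an immunoglobulin chaperone, by 0.73 ± 0.13 (adjusted p = 0.00998; without replicate 3 adjusted p = 0.0666). Of 15 neutrophil and granulocyte markers, 3 fell over all genes and 8 adjusted over the list alone (median −0.80, camera adjusted p = 0.000104, adjusted p = 0.485 with an estimated correlation). Of 15 monocyte and macrophage markers, 2 fell over all genes and 3 adjusted over the list alone (median −0.36, camera adjusted p = 0.0114, adjusted p = 0.525 with an estimated correlation; without replicate 3 camera adjusted p = 0.0564). Without replicate 3 the medians were −0.43 for neutrophil and −0.16 for monocyte markers, and without replicate 2 −0.57 for monocyte markers. As mean shares of assigned reads with vehicle and at 500 nM, neutrophil markers were 0.0170 ± 0.0225% and 0.00693 ± 0.00748% (SD; lower in 4 of 4 donors, exact p = 0.125). Monocyte markers were 0.0296 ± 0.0346% and 0.0192 ± 0.0184% (lower in 3 of 4, exact p = 0.625). Replicate 3 carries most of this: without it the neutrophil share was 0.00635% with vehicle and 0.00560% at 500 nM, and the monocyte share 0.0137% and 0.0152%. Without replicate 1 the shares at 500 nM were 0.00409% and 0.0126%.

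The share of immunoglobulin genes in the patient libraries was 22.7 ± 7.13% (SD, n = 4) with vehicle, 20.7 ± 7.67% at 50 nM and 18.2 ± 6.42% at 500 nM. It was lower in 4 of 4 donors at either dose (changes −1.95 and −4.47 points, exact p = 0.125 for each, the smallest p that 4 pairs can give). In the lines the share was 15.3 ± 8.34% with vehicle and 14.6 ± 7.74% at 100 nM (lower in 4 of 5, exact p = 0.188). The line shares are of TPM and the patient shares of assigned reads, so their levels cannot be compared. As single genes, 0 of 14 tested immunoglobulin constant region genes changed at 500 nM in limma, over all genes or adjusted over the list alone (median 0.09, camera adjusted p = 0.428).

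Of 48 cytosolic ribosomal protein genes, 32 fell at 500 nM over all genes and 46 adjusted over the list alone (median −0.29, camera adjusted p = 3.20e-17, adjusted p = 0.329 with an estimated correlation). RPL23 fell by 0.44 ± 0.07 (adjusted p = 0.00695; without replicate 2 adjusted p = 0.0608). Of 23 NF-kB targets, 9 rose over all genes and 10 adjusted over the list alone (median 0.35, camera adjusted p = 6.34e-06, adjusted p = 0.329 with an estimated correlation). CCL3 is among them. Of 20 immediate early genes, 8 rose over all genes and 10 adjusted over the list alone (median 0.30, camera adjusted p = 5.53e-05, adjusted p = 0.329 with an estimated correlation). The MAP kinase phosphatase DUSP1 rose by 0.97 ± 0.09 (adjusted p = 0.00250) and the transcription factor KLF6 by 1.12 ± 0.14 (adjusted p = 0.00378).

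Over all genes at 500 nM, limma called 2779 of 17913, 1458 higher and 1321 lower, with 89 at least 2-fold higher and 36 at least 2-fold lower, and 5886 at an unadjusted p under 0.05. With values as deposited 76.4% of 3268 changed genes were higher, against 52.5% with scaling. The count was 0 without the block on donor, 1275 with no filter on low values, 138 with only the 8 libraries compared, and 679, 468 and 547 without replicate 1, 2 or 3. Of 35 lists 23 passed with the preset correlation and 0 with an estimated correlation.

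In patient samples at 50 nM limma called 0 genes, with 2333 at an unadjusted p under 0.05 and 148 called by voom, and the sterol list had the highest median of the lists tested. SQSTM1 was at 0.91 ± 0.13 (143 to 277 RPKM, adjusted p = 0.106, higher in 4 of 4 donors), INSIG1 at 1.33 ± 0.26 (adjusted p = 0.141) and FLCN at 0.74 ± 0.12 (adjusted p = 0.126). Adjusted over the list alone, 22 of 24 genes of cholesterol synthesis and uptake rose (median 0.76, camera adjusted p = 2.06e-21, adjusted p = 0.274 with an estimated correlation). By the same measure 43 of 48 ribosomal protein genes fell (median −0.24, camera adjusted p = 1.51e-26, adjusted p = 0.277 with an estimated correlation).

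Other lists at 50 nM had medians nearer 0 than the sterol list. Adjusted over the list alone, 9 of 18 vacuolar ATPase subunits rose (median 0.23, camera adjusted p = 3.89e-06, adjusted p = 0.274 with an estimated correlation). So did 6 of 19 NRF2 and oxidative stress genes (median 0.25, camera adjusted p = 6.89e-07, adjusted p = 0.274 with an estimated correlation) and 4 of 15 fatty acid synthesis genes (median 0.18, camera adjusted p = 3.89e-06, adjusted p = 0.274 with an estimated correlation). Of 23 plasma cell identity genes 5 fell adjusted over the list alone (median −0.20, camera adjusted p = 3.51e-05, adjusted p = 0.154 with an estimated correlation). CD27 was at −0.40 ± 0.07 (adjusted p = 0.132) and the transcription factor IRF4 at −0.42 ± 0.10 (adjusted p = 0.177). Monocyte and macrophage markers stood beside these at a median of −0.28, with 1 of 15 lower adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.629 with an estimated correlation). Of 30 unfolded protein response genes 4 fell adjusted over the list alone (median −0.11, and −0.049 without replicate 1, camera adjusted p = 7.49e-05, adjusted p = 0.374 with an estimated correlation). Of the control genes VAC14 was at 0.35 ± 0.12 (adjusted p = 0.263), PIKFYVE at 0.14 ± 0.09, TFE3 at 0.13 ± 0.08, FIG4 at 0.09 ± 0.10 and TFEB at −0.08 ± 0.10.

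Of 17913 genes limma called 0 at 50 nM (smallest adjusted p = 0.106), with 2333 at an unadjusted p under 0.05, and voom called 148, 94 higher and 54 lower. Without the block on donor the count was also 0, with only the 8 libraries compared it was 1, and with protein-coding genes alone 6. Of 35 lists 23 passed with the preset correlation and 0 with an estimated correlation.

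Between 500 nM and 50 nM, heat shock and sterol genes had the highest median differences of the lists tested, and neutrophil markers the lowest. The 13 heat shock genes were at 0.60, with 0 past the threshold adjusted over the list alone (camera adjusted p = 5.35e-06, adjusted p = 0.419 with an estimated correlation). Of 24 sterol genes 13 were higher at 500 nM adjusted over the list alone (0.49, camera adjusted p = 7.36e-12, adjusted p = 0.419 with an estimated correlation). So were 11 of 19 NRF2 and oxidative stress genes (0.32, adjusted p = 0.317 with an estimated correlation) and 6 of 23 NF-kB targets (0.38, adjusted p = 0.317 with an estimated correlation). The same was true of 5 of 20 immediate early genes (0.31, adjusted p = 0.419 with an estimated correlation). Markers of other cell types passed with camera at the preset correlation, but not with an estimated one. The 15 neutrophil markers were at −0.53 (camera adjusted p = 0.00021, adjusted p = 0.496 with an estimated correlation). The 11 T cell markers were at 0.15 (camera adjusted p = 0.0131, adjusted p = 0.493 with an estimated correlation). Of either list 0 members were past the threshold adjusted over the list alone. No single gene differed in limma (0 of 17913, smallest adjusted p = 0.116), with 2291 at an unadjusted p under 0.05 and 53 called by voom. Without the block on donor the count was also 0.

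The genes called in lines at 100 nM and in patient samples at 500 nM overlap among those that rose. Of 47 line genes and 1261 patient genes that rose, among 14030 tested in both, 22 are shared against 4.22 for independent lists (Fisher's exact p = 1.32e-11 across genes, which are not independent). They include RRAGC, FLCN, NEU1, NPC2, TMEM55B, VPS18, MVD and PIP4K2C, described above, and also, named after their values were seen, HPS1, a factor of lysosome-related organelles, and PQLC2, a lysosomal amino acid exporter. Of genes that fell, 1 is shared, RP5-1160K1.6, against 0.385 for independent lists (Fisher's exact p = 0.330), and 0 genes were called in opposite directions. Of the 47 line genes, 43 had the same sign at 500 nM. With values as deposited, or at an adjusted p under 0.01, limma leaves no line gene to share and the overlap is 0, against 3688 line genes at an unadjusted p under 0.05 and 30 shared genes with the patient calls of voom.

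The response of some heat shock genes differed in limma between the lines at 100 nM and the patient samples at 500 nM. The line change minus the patient change was −2.61 ± 0.52 for HSPA6, which is not on the heat shock list (adjusted p = 0.0372), and −2.22 ± 0.42 for HSPA1B (adjusted p = 0.0353). It was −2.17 ± 0.46 for HSPA1A (adjusted p = 0.0420) and −1.48 ± 0.31 for HSP90AA1 (adjusted p = 0.0424), from 5 lines and 4 donors. Of the 13 genes on the list 3 were lower in this difference over all genes, HSPA1B, HSPA1A and HSP90AA1, and 12 adjusted over the list alone (median −1.21, adjusted p = 0.334 with an estimated correlation). In the other direction, SNORD42A, inside its host RPL23A, was at 2.20 ± 0.33 (adjusted p = 0.0143) and MIR148A, a microRNA gene, at 1.93 ± 0.37 (adjusted p = 0.0353). The entry mascRNA-menRNA was at 1.66 ± 0.36 (adjusted p = 0.0430) and SH2D3C, an adaptor protein gene, at 1.26 ± 0.24 (adjusted p = 0.0365).

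Each of these 8 calls was lost without at least 2 of the lines or donors, left out 1 at a time. Without line replicate 1, 2, 3 or 5, adjusted p was 0.0544, 0.0692, 0.0575 and 0.0703 for HSPA6, 0.0613, 0.0762, 0.0682 and 0.0716 for HSP90AA1, 0.0645, 0.0762, 0.0667 and 0.0652 for mascRNA-menRNA, and 0.0544, 0.0685, 0.0516 and 0.0624 for SH2D3C. HSPA1A missed without any 1 of line replicates 1 to 5 (0.0544, 0.0762, 0.0682, 0.0533 and 0.0716). Without line replicate 2, 3 or 5 it was 0.0663, 0.0575 and 0.0624 for HSPA1B and 0.0685, 0.0575 and 0.0633 for MIR148A. Without patient replicate 1, 2 or 3 it was 0.127, 0.144 and 0.111 for HSPA6, 0.124, 0.140 and 0.102 for HSPA1B, 0.150, 0.146 and 0.111 for HSPA1A, and 0.150, 0.134 and 0.0896 for HSP90AA1. For MIR148A these were 0.119, 0.108 and 0.0928, and for SH2D3C 0.127, 0.138 and 0.111. The entry mascRNA-menRNA missed without patient replicate 2 or 3 (0.146 and 0.123), and SNORD42A without patient replicate 1 or 3 (0.0809 and 0.0704).

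Of 30 unfolded protein response genes 5 were higher in this difference over all genes and 18 adjusted over the list alone (median 0.32, adjusted p = 0.334 with an estimated correlation). Of 18 NRF2 genes 5 were lower over all genes and 12 adjusted over the list alone (median −0.42, adjusted p = 0.334 with an estimated correlation). Both of these lists and the heat shock list passed with camera at the preset correlation and with fry. The vacuolar ATPase and the TFEB lists had a median difference of 0.02 each and did not pass (adjusted p = 0.796 with an estimated correlation). Other lysosomal lists had medians above 0 in this difference. The 38 entries for hydrolases were at 0.23, with 1 lower over all genes, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.21e-05, adjusted p = 0.472 with an estimated correlation). The 25 entries for membrane proteins were at 0.20, with 0 past limma's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.488 with an estimated correlation).

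In all, 257 of 14030 genes differed at 500 nM, 111 higher and 146 lower, with 3277 at an unadjusted p under 0.05. Against patient samples at 50 nM 1 gene differed, SAT2, a thialysine acetyltransferase (1.07 ± 0.12, adjusted p = 0.0102), with 1738 at an unadjusted p under 0.05. Without line replicate 1 its adjusted p was 0.0645, and without patient replicate 1, 2, 3 or 4 it was 0.195, 0.0849, 0.0648 and 0.0537. The 257 became 0 without the block on line or donor, 80 with no filter, 1500 with values as deposited, 130 higher and 1370 lower, and 694 with protein-coding genes alone, 349 higher and 345 lower. The even split of directions thus rests on scaling. The 257 became 129, 66, 50 and 55 without line replicate 1, 2, 3 or 5, and 13, 8, 9 and 1061 without patient replicate 1, 2, 3 or 4. Dose, unit of the values and RNA kit also differ between lines and patient samples, so a difference cannot be assigned to the kind of cell.

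**Figure D1:**
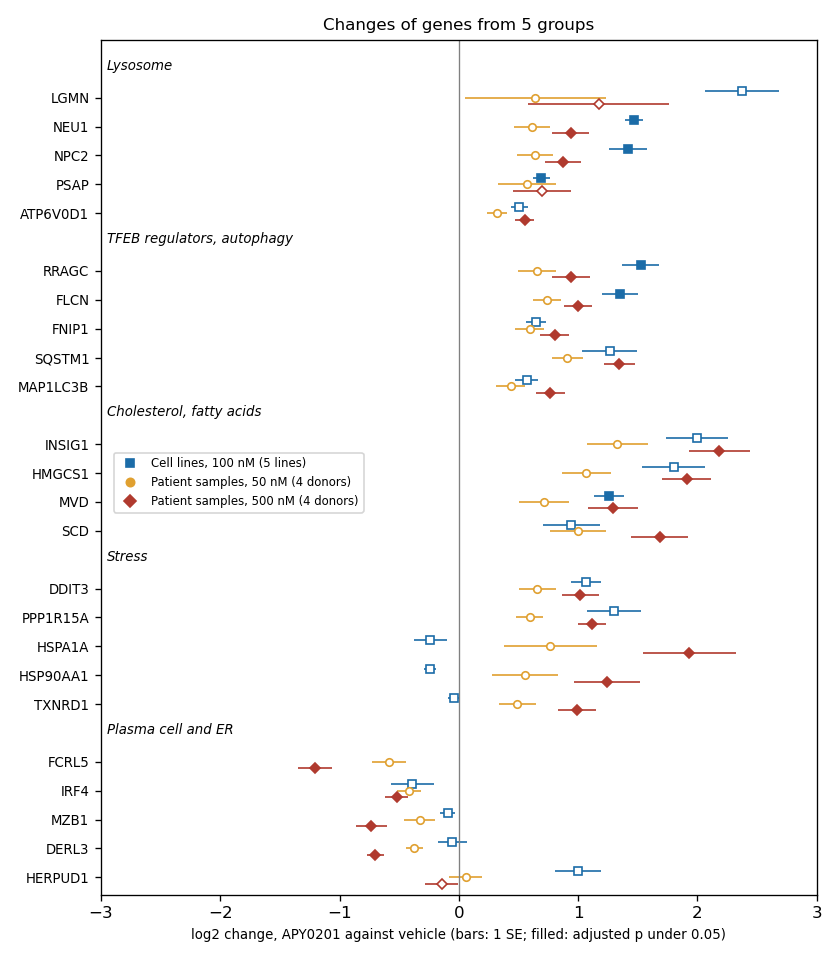
Log2 change of 24 genes from 5 groups: squares for the 5 lines at 100 nM, circles for patient samples at 50 nM and diamonds for patient samples at 500 nM (4 donors), with bars of 1 standard error and filled symbols for an adjusted p under 0.05. INSIG1 lies at 1.995, 1.33 and 2.18, and HSPA1A at −0.24, 0.77 and 1.93.

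**Figure D2:**
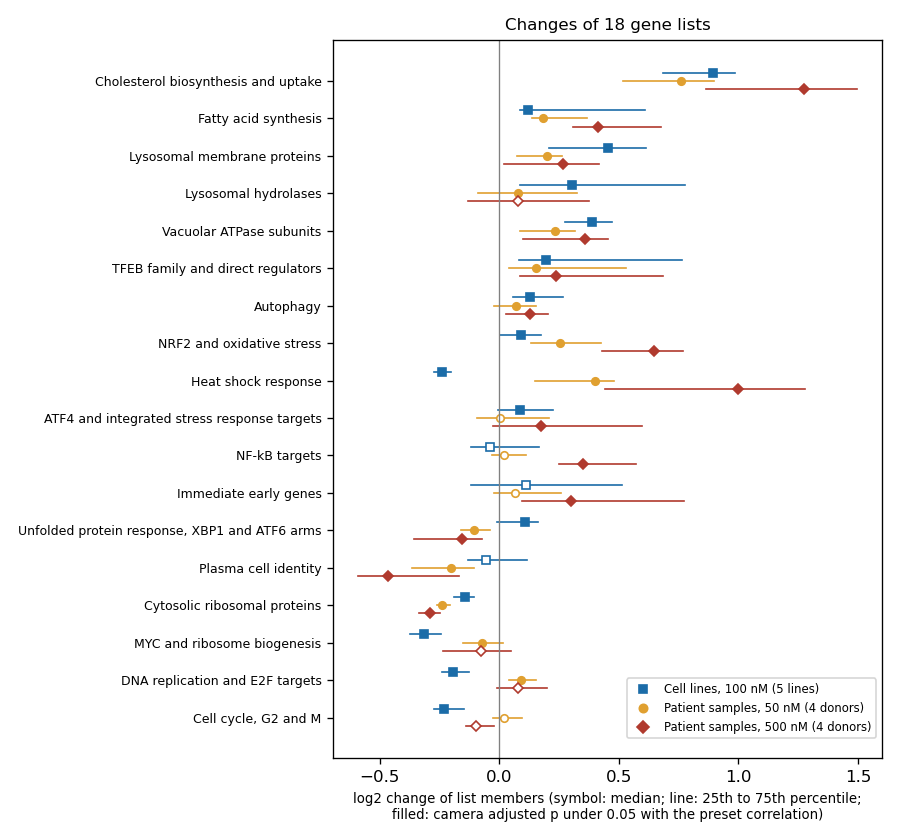
Median log2 change of 18 gene lists (symbols as for the single genes) with lines from the 25th to the 75th percentile of members, filled where the camera adjusted p with the preset correlation is under 0.05; with an estimated correlation none passed. Sterol genes have medians of 0.89, 0.76 and 1.27, and ribosomal protein genes of −0.15, −0.24 and −0.29.

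**Figure D3:**
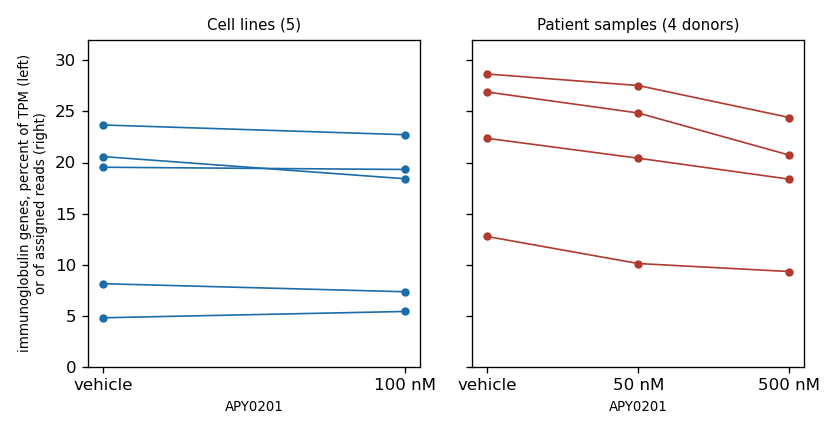
Immunoglobulin genes as a percent of TPM in the 5 lines and as a percent of assigned reads in the samples of 4 donors, with 1 line per cell line or donor and the dose on the horizontal axis. Means are 15.3% and 14.6% in lines with vehicle and 100 nM, and 22.7%, 20.7% and 18.2% in patient samples with vehicle, 50 nM and 500 nM.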

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

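The tests of heat shock genes, of myeloid markers and of the ribosomal RNA repeat entry below were chosen after the result was seen; the idea of the short-gene test came after the count for protein-coding genes alone had been seen, though its outcome had not. The counts over other splits were planned.

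The heat shock list had a median difference of −1.21 between the lines at 100 nM and the patient samples at 500 nM. It was flagged because it passed with camera at the preset correlation and with fry, but it did not pass with an estimated correlation. Its members HSPA1B, HSPA1A and HSP90AA1 were at −2.22, −2.17 and −1.48, and HSPA6, which is not on the list, at −2.61. Scaling as the source is argued against, since the median at 500 nM was at least 0.99 with values as deposited and with median-of-ratios scaling. Nor did the list median rest on 1 donor alone, since it stayed at 0.64 or more without each donor in turn. The lowest donor median was negative, though, so a rise in every donor is not shown. The calls of HSPA6, HSPA1A and HSPA1B over all genes were lost without replicate 1, 2 or 3 (adjusted p = 0.0770 to 0.0896, 0.0803 to 0.101 and 0.0668 to 0.0825). Dose stays open: the list lay lower in lines at 100 nM than in patient samples at 50 nM, by a median of −0.49, with a directional fry rotation p of 0.0822 that misses 0.05. The unit of the values and the RNA kit are confounded with the kind of sample, so a difference in how primary cells and lines respond may be, but need not be, part of it.

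Granulocyte and monocyte markers had medians below 0 in patient samples at 500 nM while plasma cell genes also fell. These lists passed with camera at the preset correlation, but none passed with an estimated correlation. The monocyte list also missed without replicate 3 and without the block on donor. Fewer myeloid cells may be the source: over 30 markers the highest of the 4 donor medians was −0.051, so all 4 were below 0, but taken alone the neutrophil list was above 0 in 1 donor (0.019), the monocyte list in 1 donor (0.13), and the share of monocyte markers was lower in 3 of 4. A loss of cells and lower expression in the same cells both stay open, since bulk libraries do not separate them. A gain in the share of plasma cells alone would raise plasma cell genes, but 10 of these fell while 1 rose. Lower expression of these genes in each cell could hide such a gain, so it stays open. The markers are a small part of the libraries, 0.0170% of reads for neutrophil markers and 0.0296% for monocyte markers with vehicle, and these means rest on replicate 3, without which they were 0.00635% and 0.0137%.

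In the lines 54 genes passed the threshold while 3688 had an unadjusted p under 0.05. A candidate explanation is the spread of short genes, which enters the variance estimate that all genes share: without genes shorter than 300 bases, 231 protein-coding genes passed, 176 of them higher, against 37, and the prior degrees of freedom were 2.47 against 1.87. A split of the lines by the ribosomal RNA repeat entry AL353644.10 was also looked at, since it took 7.42 ± 9.47% of TPM with vehicle, from 0.481% to 20.1%. When JJN3 and RPMI-8226, with much of it, and the other 3 lines were scaled apart, 100% of the genes that rose were higher in each line of either set; these genes were picked because they rose in the same 5 lines, so this decides nothing and such a split stays open.

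Differences between the lines at 100 nM and the patient samples at 500 nM numbered 257. This was the most among 100 assignments of the 9 lines and donors to sets of 5 and 4, where the highest other count was 16. Every other assignment mixes lines and donors in at least 1 set, so a true difference would add to its spread and hold its count down. The 257 became 13, 8, 9 and 1061 without patient replicate 1, 2, 3 or 4, so the count also rests on single donors. Beside the heat shock genes, the largest were SNORD42A (2.20), MIR148A (1.93), mascRNA-menRNA (1.66) and SH2D3C (1.26). Among lists, the unfolded protein response differed by a median of 0.32, NRF2 and oxidative stress by −0.42, DNA replication by −0.27, plasma cell identity by 0.26 and class II antigen presentation machinery by 0.35. These 5 lists were flagged because they passed with camera at the preset correlation and with fry. Their adjusted p with an estimated correlation was 0.334, 0.334, 0.385, 0.381 and 0.334. Against patient samples at 50 nM 1 gene differed, SAT2 (1.07), and 4 of the 100 assignments gave as many, with 18 as the highest other.

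In 11 of 304 groups of 4 or 5 changes 1 value stood far from the others; chance alone gives about 1 in 20 groups, and 3.62% were found. In the lines, 1 of the 5 had NUSAP1, a spindle protein, at −0.19 (others −0.42 to −0.37), 1 had a glycolysis median of −0.43 (others −0.11 to −0.06) and 1 a plasma cell identity median of −0.37 (others 0.02 to 0.06). At 50 nM, 1 of the 4 donors had TXN at 0.21 (others 0.53 to 0.59), 1 a median of −0.94 for cholesterol efflux genes (others −0.16 to −0.05) and 1 a median of −0.19 for megakaryocyte markers (others 0.00 to 0.02). At 500 nM, 1 of the 4 had ITGA8 at −3.52 (others −1.11 to −0.86), 1 had NPC2 at 1.42 (others 0.66 to 0.71), and medians stood apart for the unfolded protein response (−0.43, others −0.15 to −0.09), for G2 and M phase (−0.43, others −0.03 to 0.04) and for cholesterol efflux (−0.95, others −0.04 to 0.08).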

How the results depend on the processing

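No scaling at all, pseudocounts, protein-coding genes alone and the 2 sets of lines were chosen after the data were seen; the cause of a change below was not tested unless it is named. The planned count-model alternatives were not run. For lines TPM keeps no depth, so voom was not run there or for the line and patient differences. The reads recovered for patient samples would have allowed count models, but only voom was run on them. In the lines 54 genes became 0 with no filter, 0 without the block on line, 0 with values as deposited, 0 to 0 without each replicate in turn, 2 with a pseudocount of 0.1, 816 with protein-coding genes alone, 0 with KMS26, L363 and EJM alone and 0 with JJN3 and RPMI-8226 alone (fewer libraries), against 3688 at an unadjusted p under 0.05 in limma; median-of-ratios scaling gave 52. At 50 nM 0 became 148 with voom, 1 with only the 8 libraries compared and 6 with protein-coding genes alone, with 0 to 0 without each replicate and 2333 at an unadjusted p under 0.05 in limma. At 500 nM 2779 became 1275 with no filter, 0 without the block on donor, 138 with only the 8 libraries, and 468 to 2415 without each replicate, lowest without replicate 2; median-of-ratios scaling gave 2776 and voom 3687. Between the doses 0 became 53 with voom, with 2291 at an unadjusted p under 0.05 in limma. Of the differences from the lines, 257 became 80 with no filter, 0 without the block, 1500 with values as deposited, 694 with protein-coding genes alone, and 8 to 1061 without each line or donor (8 without patient replicate 2, 1061 without patient replicate 4), and 1 became 0 without the block, 0 with a pseudocount of 0.1 and 0 to 1 without each line or donor.

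With an estimated correlation 19, 23 and 23 lists in the lines, at 50 nM and at 500 nM became 0, 0 and 0 (smallest adjusted p = 0.412, 0.154 and 0.119), and with fry 10, 6 and 16; without each replicate they were 16 to 18, 19 to 23 and 21 to 25. The 23 genes shared by lines and patient samples became 0 at an adjusted p under 0.01 and 0 with values as deposited, where limma calls no line gene. Of single genes TFEB reversed to −0.11 in JJN3 and RPMI-8226 alone and, at 500 nM, ranged from −0.087 (without replicate 3) to 0.13 without each replicate, and FIG4 from −0.043 (without replicate 4) to 0.17. Of 1033 alternative values for 74 genes named at 500 nM, 785 kept direction and side of the threshold, 245 fell short of it, 1 came to pass it and 2 reversed. In the lines these were 620, 232, 28 and 1 of 881 values for 59 genes, and at 50 nM 795, 0, 17 and 0 of 812 for 58 genes. No gene passed at 50 nM in the main fit, so none could fall short there. That tally cannot be set beside the others as a measure of robustness. In the lines and at 500 nM too, a gene that missed the threshold in the main fit counts as kept when it misses again. In the lines every named gene past the threshold lost its call in each setting that gave 0 genes. The share of values kept is thus no measure of how robust the calls are. Without immunoglobulin genes in the denominator, the changes in the shares of mitochondrially encoded genes and of the 8 sets of cell type markers kept their sign; at 500 nM those of AL353644.10 (0.0048 to −0.0047 points) and of entries on other contigs (0.0050 to −0.0047) did not. Depth limits the lines in an unknown way, and in patient samples 36.9 M reads or more were assigned per library.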

Other observations

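The counts over other splits below were planned, and only the medians with values as deposited or without a line or donor were added after the data were seen.

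Several lists beyond those described above were tested in the lines. Genes encoded by mitochondrial DNA had a median of 0.38, with 0 of 13 past limma's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.000107, adjusted p = 0.445 with an estimated correlation), and their share of TPM was 13.6 ± 1.94% with vehicle and 17.7 ± 5.35% at 100 nM (higher in 4 of 5, exact p = 0.125). Cytosolic ribosomal proteins were at −0.15 (0 of 48 over all genes or adjusted over the list alone, adjusted p = 0.445 with an estimated correlation). The unfolded protein response was at 0.10, with 0 of 30 over all genes and 4 higher adjusted over the list alone (adjusted p = 0.445 with an estimated correlation), and among its members HERPUD1 was at 0.997 (adjusted p = 0.0826) and SEL1L at 0.52 (adjusted p = 0.0583). ATF4 targets were at 0.09 (2 higher adjusted over the list alone, adjusted p = 0.625 with an estimated correlation; camera adjusted p = 0.0141, and 0.142 and 0.473 without replicate 3 or 4), with PPP1R15A at 1.30 (adjusted p = 0.0711). Interferon genes were at 0.17 and NRF2 genes at 0.09 (1 higher each adjusted over the list alone, adjusted p = 0.445 with an estimated correlation), and glycolysis at −0.13 (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.602 with an estimated correlation). With camera and the preset correlation these 3 also passed (adjusted p = 0.0266, 0.0296 and 0.0318) but interferon missed without replicate 1, 2, 3 or 5 (adjusted p = 0.132, 0.136, 0.0924 and 0.0753), NRF2 without replicate 1 or 2 (0.0643 and 0.101) and glycolysis without replicate 3 (0.149).

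Lists that did not pass with camera in the lines had medians of 0.02 for class II machinery (−0.03 with values as deposited), 0.08 for p53 targets, 0.05 for apoptosis regulators, 0.11 for immediate early genes, 0.01 for the nuclear encoded respiratory chain (−0.05 with values as deposited), −0.05 for metal handling (mean 0.11), −0.05 for plasma cell identity, −0.03 for immunoglobulin constant regions, −0.01 for cholesterol efflux and −0.04 for NF-kB targets (mean 0.19). The NF-kB list holds CCL3, at 3.42 ± 0.56 in 5 of 5 lines (adjusted p = 0.0695), beside NFKBIA, the inhibitor of the pathway, at −0.33 (adjusted p = 0.0650). The markers of T cells, natural killer cells, monocytes, neutrophils, erythroid cells, B cells, megakaryocytes and stromal cells had too few genes above the filter for a list test in the lines. As mean shares of TPM with vehicle and at 100 nM, T cell markers were 0.00329% and 0.00437%, and B cell markers 0.00406% and 0.00502%. Each was higher in 5 of 5 lines (exact p = 0.0625, the smallest that 5 pairs can give), and the other 6 sets had an exact p of 0.438 or more.

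In patient samples at 500 nM, 4 of 21 glycolysis genes rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone (median 0.26, adjusted p = 0.490 with an estimated correlation; camera adjusted p = 0.00350, and 0.129 without replicate 1), with the glucose carrier SLC2A1 at 0.75 ± 0.12 (adjusted p = 0.00745; 0.0565 without replicate 2). Of 31 nuclear encoded genes of the respiratory chain 6 fell over all genes and 7 adjusted over the list alone (median −0.07, but 0.03 with values as deposited, adjusted p = 0.524 with an estimated correlation). For this list camera adjusted p was 0.00395, and 0.129 without replicate 1, and the camera call was also lost with values as deposited. ATP5A1, of the ATP synthase, was at −0.34 ± 0.05 (adjusted p = 0.00718, and 0.0617 without replicate 2). Mitochondrially encoded genes were at 0.21 with 0 of 13 past limma's threshold over all genes (adjusted p = 0.593 with an estimated correlation; camera adjusted p = 0.0212, and 0.671 without replicate 1). Of 10 metal handling genes 4 rose, over all genes and adjusted over the list alone (median 0.30, adjusted p = 0.329 with an estimated correlation; camera adjusted p = 0.0203, and 0.0872 without replicate 2).

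The other lists at 500 nM had medians of −0.08 for MYC and ribosome biogenesis (6 of 32 fell; 0.01 with values as deposited), 0.08 for DNA replication (3 of 30 rose), 0.13 for apoptosis regulators (3 of 21 rose and 1 fell), −0.10 for G2 and M phase, 0.06 for p53 targets (3 of 20 rose), −0.27 for class II machinery (1 of 9 rose and 2 fell), −0.13 for cholesterol efflux, −0.00 for interferon genes (mean 0.01), −0.21 for B cell markers and 0.10 for megakaryocyte markers, and did not pass with camera. These counts are over all genes. Adjusted over the list alone, 2 DNA replication genes rose, 1 class II gene rose and 4 fell, 2 of 9 B cell markers rose and 2 fell, and the others had the same counts. T cell markers were at 0.24, with 1 of 11 higher over all genes and adjusted over the list alone (adjusted p = 0.524 with an estimated correlation). Their camera adjusted p was 0.0454, and 0.182 and 0.217 without replicate 1 or 3. The camera call was also lost without the block on donor and with values as deposited. The lists of stromal and endothelial, erythroid and natural killer cell markers had too few tested members in patient samples.

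Some mean shares of assigned reads rest on 1 donor. With vehicle, at 50 nM and at 500 nM, T cell markers were 0.0234%, 0.0306% and 0.0290% (SD 0.0379, 0.0505 and 0.0452), but 0.00454%, 0.00545% and 0.00644% without replicate 4. Erythroid markers were 0.0190%, 0.0140% and 0.0131% (SD 0.0299, 0.0199 and 0.0167), but 0.00412%, 0.00419% and 0.00497% without replicate 4. Stromal and endothelial markers were 0.0189%, 0.0166% and 0.0118% (SD 0.0211, 0.0174 and 0.00934), but 0.00857%, 0.00816% and 0.00765% without replicate 3. Natural killer cell markers were 0.00558%, 0.00613% and 0.0116% (SD 0.00668, 0.00508 and 0.0104), with 0.00225% and 0.00368% with vehicle and at 50 nM without replicate 3. Megakaryocyte markers were 0.00633%, 0.00765% and 0.00930% (SD 0.00667, 0.00794 and 0.00983), with 0.00387% with vehicle without replicate 3 and 0.00577% at 500 nM without replicate 1. B cell markers were 0.0145%, 0.0153% and 0.0144% (SD 0.00549, 0.00519 and 0.00377).

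At 50 nM the lists not yet given had medians of 0.20 for lysosomal membrane proteins (4 rose and 2 fell adjusted over the list alone, adjusted p = 0.374 with an estimated correlation), 0.08 for lysosomal hydrolases (0.654), 0.15 for the TFEB family (0.234), 0.07 for autophagy (0.274), 0.09 for endosomal genes (0.161), 0.15 for phosphoinositide enzymes (0.351), 0.09 for DNA replication (0.654), −0.12 for interferon genes (0.654), −0.27 for cholesterol efflux (0.374), −0.07 for MYC and ribosome biogenesis (0.654), 0.17 for mitochondrially encoded genes (0.654), 0.06 for glycolysis (0.654), 0.40 for heat shock (0.654), 0.22 for metal handling (0.379) and −0.19 for neutrophil markers (0.679), each with that adjusted p with an estimated correlation. Adjusted over the list alone, 1 of 43 entries for hydrolases (IDS has 2), 3 of 14 in the TFEB family, 1 of 37 autophagy genes, 3 of 32 endosomal genes, 2 of 12 phosphoinositide enzymes, 2 of 21 glycolysis genes and 3 of 10 metal handling genes rose and 1 of 15 neutrophil markers fell, with 0 in the other lists named here; over all genes limma called 0 members of any list at 50 nM. These lists passed with camera and the preset correlation, but some missed in part: without replicate 1 glycolysis (adjusted p = 0.605), heat shock (0.309), metal handling (0.0739) and interferon genes (0.0760); without replicate 2 heat shock (0.0910), metal handling (0.108) and mitochondrially encoded genes (0.0694); without replicate 3 cholesterol efflux (0.0992) and neutrophil markers (0.419); and without replicate 4 hydrolases (0.251), DNA replication (0.296) and MYC (0.771). Those that did not pass with camera were immediate early genes (0.07), apoptosis regulators (0.08), ATF4 targets (0.00), p53 targets (0.03), the respiratory chain (−0.02), NF-kB targets (0.02), immunoglobulin constant regions (−0.07), G2 and M phase (0.02), class II machinery (−0.11, mean 0.02), T cell markers (−0.04, mean 0.03), B cell markers (−0.03, mean 0.01) and megakaryocyte markers (0.02).

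Leaving out 1 line or donor moved the median of some lists above by over 1.5 times. In the lines without replicate 1, ATF4 targets were at 0.16 and interferon genes at 0.099; without replicate 2, ATF4 targets were at 0.16, the unfolded protein response at 0.058, NRF2 genes at 0.035 and interferon genes at 0.11. Without replicate 3 glycolysis was at −0.050 and ATF4 targets at 0.031, and without replicate 4 ATF4 targets at 0.012. At 500 nM without replicate 1, glycolysis was at 0.076, the respiratory chain at −0.023, mitochondrially encoded genes at 0.0059 and T cell markers at 0.11. Without replicate 4 the respiratory chain was at −0.11, mitochondrially encoded genes at 0.33 and metal handling at 0.57.

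At 50 nM without replicate 1, glycolysis was at 0.0033, mitochondrially encoded genes at 0.080, heat shock at 0.26, MYC and ribosome biogenesis at −0.13, interferon genes at −0.075 and neutrophil markers at −0.31. Without replicate 2, hydrolases were at 0.14, glycolysis at 0.092, heat shock at 0.24 and neutrophil markers at −0.30. Without replicate 3, hydrolases were at 0.12, cholesterol efflux at −0.095, interferon genes at −0.20 and neutrophil markers at −0.041. Without replicate 4, hydrolases were at 0.025, lysosomal membrane proteins at 0.085, glycolysis at 0.12, DNA replication at 0.043, neutrophil markers at −0.31 and MYC and ribosome biogenesis, with its sign turned, at 0.0093.

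Other splits of the same libraries were counted for each comparison. In the lines 1 of 100 splits, the real one, gave as many as 54 genes (highest other 5), and 1 of 100 gave 19 lists (highest other 18). At 500 nM 1 of 35 splits gave 2779 genes (highest other 0), and at 50 nM 1 of 35 gave 23 lists (highest other 21). Most of these splits put both libraries of at least 1 line or donor in the same group. All splits were fitted with the same block, and in all but the real one the drug effect adds to the spread. The low gene counts of the other splits are thus partly built in, and these counts do not exclude chance. For the 23 lists at 500 nM chance is not excluded either, since 4 of 35 splits gave as many (highest other 27). At 50 nM, where limma called 0 genes with 2333 at an unadjusted p under 0.05 and 148 called by voom, 35 of 35 splits gave as many (highest other 1). Between the doses, with 0 genes, 2291 at an unadjusted p under 0.05 and 53 by voom, 35 of 35 did (highest other 0). Every split reaches a count of 0, so these 2 counts say nothing about chance.

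Only 16 splits in lines and 8 in donors part every pair as the real one does, too few for a share under 0.05. The highest others there were 0 genes and 17 lists in lines against 54 and 19, 1 gene and 19 lists at 50 nM against 0 and 23, and 0 genes and 27 lists at 500 nM against 2779 and 23. The other splits keep the vehicle and treated library of at least 1 line or donor in the same group.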
